A study of Mus musculus with 6 samples.

How the data were processed

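RNA of 6 mouse pancreatic islet samples, labelled as beta cells, was measured in 2 groups of 3 libraries, control (labelled wild type) and Bcas2 conditional knockout (cKO), which the series design text calls a knockdown. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a SMARTer mRNA-seq kit. Per the submitters' processing notes the genome build was GRCm38 (mm10). The aligner, the counting program, their versions and the strand setting are not given in the sources used here, and neither are the Cre driver, the deleted part of Bcas2, or the age and sex of the mice.

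The deposited table holds FPKM (fragments or reads per kilobase of gene length and depth) for 54532 genes with Ensembl identifiers, coordinates, gene lengths and biotypes, 1 column per library, per the file headers; 21687 genes were at 0 in every library. Of the identifiers, 54409 were found in GENCODE M21 (GRCm38), and 98.3% of these had the same chromosome, start and end. Columns were matched to samples by name. The control columns 1, 3 and 4 and the Bcas2 cKO columns 3 and 4 match labels, but the labels name Bcas2 cKO samples 1, 3 and 4 while the table has a column numbered 5. That column was used as a member of the Bcas2 cKO group with no sample of its own, and it is called Bcas2 cKO library 5.

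FPKM times gene length was a whole multiple of 1 step per library for 100% of the values above 0, within 0.01 of a read, so the reads per gene were recovered. They came to 15170439 to 15594871 per control library and 16351800 to 16904326 per Bcas2 cKO library. The depth in the deposited FPKM was 0.890 to 1.11 times these totals, so the values also carry a scaling between libraries made by the authors, whose method is not given in the sources used here. Because the deposited unit is FPKM, the recovered reads served for depth, for floors of 3 reads and for an added alternative only. Pairs of libraries were compared with a chi-square statistic over genes with at least 50 reads in the pair. It was at least 13.6 per degree of freedom in every pair, so no library was a second copy of another.

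Genes with a mean of at least 1 FPKM over the 6 libraries (13723) were tested on log2(FPKM + 1) with limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3. A gene rose or fell when its Benjamini-Hochberg adjusted p was under 0.05, with no fold minimum. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Bcas2, Ins1 and Ins2 were also tested with a 2-sided exact permutation test. The 27 gene lists, with 746 genes found in the table, were tested with limma's camera at a preset correlation of 0.01 between genes, with an adjustment over the lists, and again with an estimated correlation and with fry. Adjustment over the list alone means a Benjamini-Hochberg adjustment over the measured members of 1 list. The lists, the tests, most other settings and the rule for choosing genes to report were fixed before the data were examined. The rule chose Bcas2, Ins1, Ins2, the 10 largest rises and 10 largest falls among called genes with no overlap between groups (predicted and clone-named genes left out), and up to 4 called members of each list with the largest change, or the 2 members of highest expression where none was called. A few of the genes chosen are not reported here.

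The settings fixed in advance were a pseudocount of 0.1, no filter beyond a mean above 0, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, rescaling without the hormone genes Ins1, Ins2, Gcg, Sst, Ppy, Pyy and Iapp, library weights, eBayes without trend or with robust estimation, a minimum absolute log2 fold change of 1, and leaving out each library. Limma voom on the recovered reads, a minimum mean of 10 recovered reads, and a block on the numbers 3 and 4 were added after the data were examined. The fit was tested on simulated data with the means and depths of these libraries, in 5 data sets of 13701 genes with 200 changed genes each. All genes were given 1 spread, the median of genes with at least 50 reads, and were independent of each other. The rates may therefore be better than in these data. The fit recovered 22.1% of the genes changed by a log2 fold of 0.5, 83.3% of those changed by 1 and 87.9% of those changed by 2. Of its calls 7.2% were false, and 5 data sets with no change gave 1 call in all. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.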

Results

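Transcripts of mouse pancreatic islet preparations labelled as beta cells, the insulin-producing cells of the islet, were measured by RNA-seq in 3 control and 3 Bcas2 conditional knockout (cKO) libraries. BCAS2 is a subunit of the Prp19 complex, which acts in the activation of the spliceosome. The series title ties the study to insulin synthesis and secretion and to alternative splicing. The comparison asks which transcripts differ when Bcas2 is reduced in these cells. The control libraries carry the numbers 1, 3 and 4 and the Bcas2 cKO libraries the numbers 3, 4 and 5. The deposited values were FPKM, from which 15170439 to 15594871 reads on genes per control library and 16351800 to 16904326 per Bcas2 cKO library were recovered. Ins1 and Ins2, the insulin genes, took 18.5 to 26.7% of these reads in control and 13.3 to 14.6% in Bcas2 cKO. Acinar cell transcripts, from the exocrine pancreas around the islets, took 0.668 to 1.62% in control and 2.16 to 6.09% in Bcas2 cKO. The first principal component held 52.6% of the variance and separated the 3 control libraries from the 3 Bcas2 cKO libraries. No pair of libraries agreed within sampling noise. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

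Bcas2 itself (ENSMUSG00000005687, chromosome 3, 103171655 to 103179166, GRCm38) was 12.2 ± 2.51 FPKM in control and 8.77 ± 0.370 FPKM in Bcas2 cKO (SD, n = 3 each). Control libraries 1, 3 and 4 held 10.3, 15.04 and 11.2 FPKM, and Bcas2 cKO libraries 3, 4 and 5 held 8.76, 8.40 and 9.14 FPKM. Every Bcas2 cKO value lay below every control value. The ratio of the means was 0.720. The log2 fold change was -0.42 (SE 0.13), with a limma adjusted p of 0.083, which did not pass the threshold of 0.05. The 2-sided exact permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 libraries allow. The labels do not say which part of the gene was deleted, and the gene total counts reads from the remaining exons and from other cells of the preparation. The adjusted p passed the threshold with the libraries rescaled without the hormone genes (0.035), with voom on the recovered reads (0.047) and without control library 1 (0.049), where the log2 fold change was -0.52, -0.45 and -0.52. Rescaling without the hormone genes also lowered the median log2 fold change of all genes, so that pass is not specific to Bcas2.

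**Figure D1:**
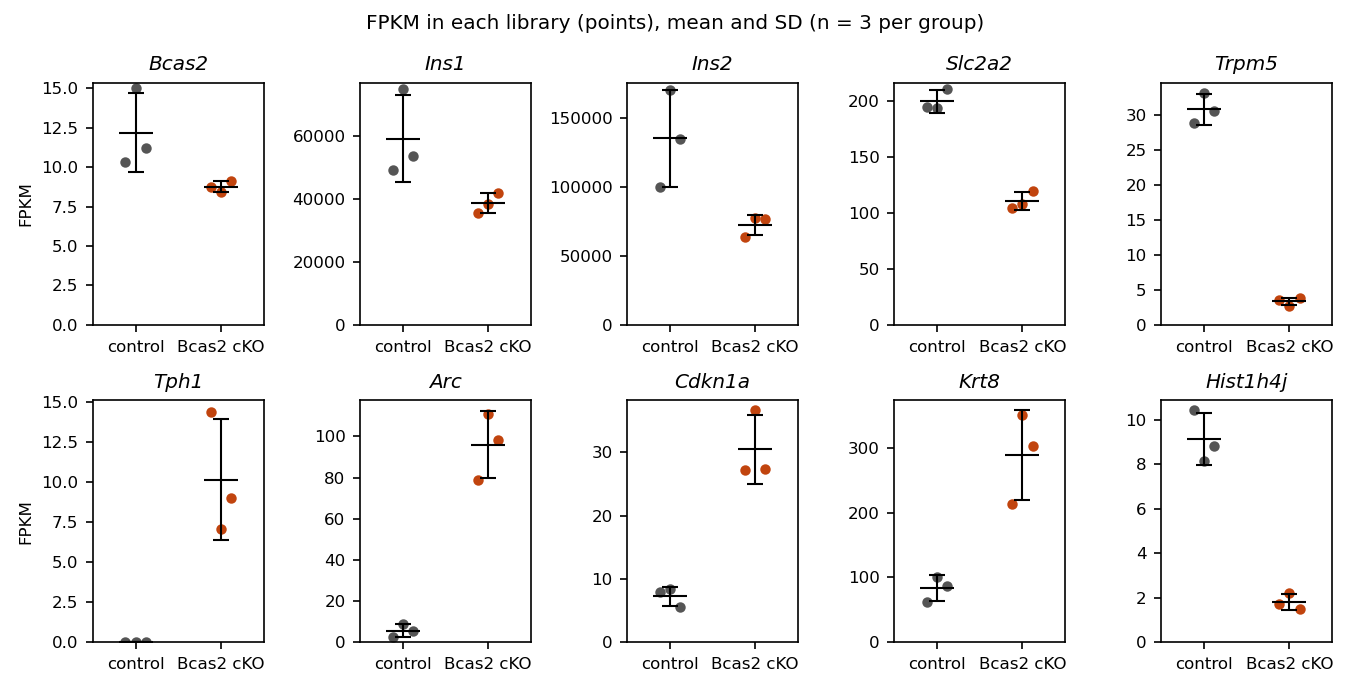
FPKM of 10 genes (vertical axes, linear from 0) in the 3 control and 3 Bcas2 cKO libraries; points are libraries, and the horizontal bar and whiskers give the mean and SD (n = 3). Bcas2 means were 12.2 and 8.77 FPKM, Trpm5 fell from 30.9 to 3.35 FPKM, and Tph1 was 0 in all 3 control libraries.

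Of the 13723 genes tested, 957 rose and 1036 fell in Bcas2 cKO (limma with trend, Benjamini-Hochberg adjusted p under 0.05), and 303 of the rises and 104 of the falls were at least 2-fold on the log2(FPKM + 1) scale. Arc, an activity-regulated gene of neurons, rose from 5.77 ± 3.05 to 95.9 ± 16.3 FPKM (SD, n = 3 each). Cldn8, a tight junction claudin, rose from 0.151 ± 0.077 to 14.9 ± 4.89 FPKM, and Nptx2, a secreted pentraxin, from 0.615 ± 0.377 to 19.0 ± 3.49 FPKM. Tph1, the enzyme that starts serotonin synthesis, had 0 reads in all 3 control libraries and 1614, 768 and 961 reads in Bcas2 cKO. Its mean of 10.2 ± 3.80 FPKM was at least 306-fold higher than the mean control value that 3 reads per library would give, a floor that covers counting error only. Trpm5, a calcium-activated cation channel of beta cells, fell from 30.9 ± 2.18 to 3.35 ± 0.558 FPKM, and Gad1, which makes the transmitter GABA, fell from 26.2 ± 4.93 to 7.62 ± 1.77 FPKM.

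Log2 fold changes of the other largest rises were 3.15 for Gbp8, a guanylate-binding protein, 2.83 for the neuropeptide gene Npy, 2.82 for Pianp, 2.74 for Sftpd, a lung surfactant collectin, and 2.70 for the matrix protein gene Matn2. The largest falls beside Trpm5 and Gad1 were Cib3 (-2.15), Wdr72 (-1.73) and 5 histone genes, Hist2h3c2 (-2.08), Hist1h2ad (-1.87), Hist1h4j (-1.85), Hist1h4h (-1.74) and Hist1h1e (-1.72). The microRNA genes Mir5710 (2.85) and Mir341 (-1.70) also ranked among the 10 largest in each direction, on at most 20 reads in any library. Histone, Gbp, amylase and trypsin genes and Ins1 and Ins2 have near-identical copies, so the division of reads among copies is uncertain. No source used here says whether counting used strand, so overlapping antisense transcripts are not excluded.

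All 1993 changed genes had no overlap between the 3 control and 3 Bcas2 cKO values, a property of 38.0% of the tested genes against 10% by chance. Rescaling without the hormone genes moved the median log2 fold change of all genes from -0.03 to -0.12, and then 613 genes rose and 1247 fell, 33.0% against 48.0% rises among calls. The count of 1993 dropped to 1318 without control library 3, 888 without control library 4, and 878, 921 and 928 without Bcas2 cKO libraries 3, 4 and 5. Of the 89 genes chosen by the rule fixed in advance that passed the test, 44 were tested without each library in turn and kept their calls. Among them were Arc, Cldn8, Nptx2, Tph1, Gbp8, Npy, Sftpd, Matn2, Trpm5, Cib3, Gad1 and the 5 histone genes. Wdr72 kept its call in the 4 of 6 fits in which its mean reached 1 FPKM. Pianp and Mir341 lost theirs in 5 of the 6 fits.

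**Figure D2:**
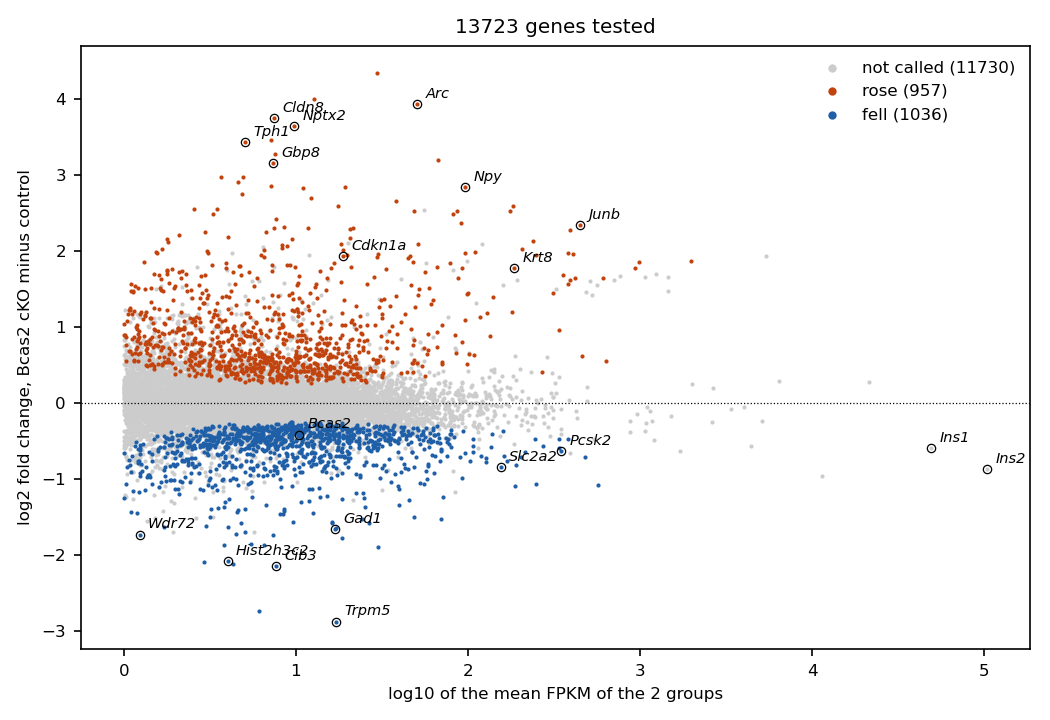
Log2 fold change of Bcas2 cKO minus control on log2(FPKM + 1) (vertical axis) against the log10 of the mean FPKM of the 2 groups (horizontal axis) for 13723 genes. Orange points rose (957), blue points fell (1036) and grey points were not called; Ins1, Ins2 and Bcas2 are among the grey points.

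More genes of beta cell identity fell than rose in Bcas2 cKO. Of the 29 measured members of that list, 9 fell, 1 rose and 19 did not pass the test (11 fell and 2 rose adjusted over the list alone). Beside Trpm5, Slc2a2, the glucose transporter of mouse beta cells, fell from 199.9 ± 9.98 to 111 ± 8.03 FPKM (log2 fold change -0.85, SE 0.10, limma adjusted p 0.0037). Ucn3, the urocortin of mature beta cells, fell from 256 ± 66.7 to 119 ± 27.5 FPKM (-1.09, SE 0.24, limma adjusted p 0.026). The member that rose was Npas4, an activity-induced transcription factor (2.52, SE 0.56). Mafa, a transcription factor of mature beta cells chosen after its values were seen, was also higher, 228 ± 37.1 and 349 ± 84.1 FPKM, and did not pass the test (log2 fold change 0.60, SE 0.20, limma adjusted p 0.090). The list's median log2 fold change was -0.27 (camera adjusted p 0.0050, adjusted p = 0.33 with an estimated correlation). Between 4 and 8 members fell when a library was left out, 4 of them without Bcas2 cKO library 3 and 5 without Bcas2 cKO library 5. The calls of Ucn3 and Npas4 were each lost in 4 of those 6 fits. The acinar share of reads, 0.668 to 1.62% in control and 2.16 to 6.09% in Bcas2 cKO, also separated the groups.

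Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381) was 135234 ± 35084 FPKM in control and 72591 ± 7462 FPKM in Bcas2 cKO (SD, n = 3 each). Ins1 (ENSMUSG00000035804, chromosome 19, 52264323 to 52265456) was 59247 ± 13893 and 38687 ± 3248 FPKM. For Ins2 the control libraries 1, 3 and 4 gave 100267, 170433 and 135003 FPKM and Bcas2 cKO libraries 3, 4 and 5 gave 63980, 77180 and 76612 FPKM. For Ins1 the values were 49087, 75078 and 53577 FPKM in control and 35568, 38443 and 42051 FPKM in Bcas2 cKO. Neither gene passed the test, with log2 fold changes of -0.87 (SE 0.62, limma adjusted p 0.38) for Ins2 and -0.59 (SE 0.48, limma adjusted p 0.44) for Ins1. The exact permutation p was 0.1 for each. Ins2 passed it without the trend in the variance (adjusted p 0.036) and both passed with voom (0.015 for Ins2 and 0.040 for Ins1), where the fold changes were nearly equal to these and the SE was 0.20 and 0.17.

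Genes of the secretory path moved in both directions, with more falls than rises. Of 18 genes of proinsulin processing and the secretory granule, 4 fell and 2 rose (7 and 3 adjusted over the list alone). Pcsk2, a proinsulin convertase, fell from 424 ± 1.96 to 274 ± 11.9 FPKM. Scg5, its chaperone, fell by 0.59 on the log2 scale and Ptprn2, a granule membrane protein, by 0.76, whereas the granin gene Vgf rose by 0.89. The list's median was -0.21 (camera adjusted p 0.030, adjusted p = 0.33 with an estimated correlation), and its call was lost without control library 1 (adjusted p 0.052) and without Bcas2 cKO library 5 (0.053). Of 41 genes of electrical excitation and exocytosis, 9 fell and 3 rose (11 and 3 adjusted over the list alone), with a median of -0.18 (camera adjusted p 0.013, adjusted p = 0.33 with an estimated correlation). Rab37 fell by 0.78, Cadps, a priming factor of dense-core vesicles, by 0.73 and Rab3b by 0.56, and the synaptotagmin gene Syt5 rose by 0.78. Pcsk2, Rab37 and Cadps kept their calls without each library in turn, Syt5 lost it without control library 4 (adjusted p 0.056). Scg5, Ptprn2, Vgf and Rab3b lost theirs in 3 to 5 of the 6 fits.

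Markers of acinar cells were higher in Bcas2 cKO, by a median log2 fold change of 1.64 over 29 genes (camera adjusted p 8.8e-11, adjusted p = 0.40 with an estimated correlation). Of these 29, 11 rose and none fell, and 27 rose adjusted over the list alone. Amy2b, an amylase locus annotated in the table as an unprocessed pseudogene, rose from 44.6 ± 23.5 to 305 ± 249 FPKM and Zg16, a zymogen granule protein, from 79.9 ± 40.8 to 333 ± 183 FPKM. Reg1 rose from 143 ± 41.6 to 618 ± 378 FPKM and Sycn from 154 ± 58.4 to 663 ± 430 FPKM. The number of members past the test was 0 without control library 3, control library 4 or Bcas2 cKO library 4, and 1 without Bcas2 cKO library 5, the library with the highest acinar share.

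Other cell types did not move alike. Among 16 macrophage and lymphocyte markers 6 rose and none fell (10 and 0 adjusted over the list alone; median 0.48, camera adjusted p 4.8e-06, adjusted p = 0.33 with an estimated correlation), including the lysosomal protein Cd68 (1.09), Cd14 (0.79) and the complement genes C1qb (0.64) and C1qc (0.60). Among 11 ductal markers the keratins Krt8, from 83.6 ± 19.9 to 289 ± 69.7 FPKM, and Krt18, from 73.1 ± 6.69 to 161 ± 20.6 FPKM, rose and none fell (4 and 1 adjusted over the list alone; median 0.31, camera adjusted p 0.0083, adjusted p = 0.33 with an estimated correlation). Of 14 endothelial markers none passed the test (limma, 0 also adjusted over the list alone), with a median of -0.02 (camera adjusted p 0.75). Plvap was 72.0 ± 9.66 and 72.3 ± 14.3 FPKM and Kdr 15.1 ± 0.635 and 13.7 ± 1.12 FPKM. Of 16 markers of alpha, delta and PP cells, Irx1 (0.51) and Irx2 (0.37) rose and the somatostatin receptor gene Sstr3 (-0.69) fell (2 and 2 adjusted over the list alone; median 0.27, camera adjusted p 0.21). The collagen gene Col6a1 (0.71) rose among 13 stellate and fibroblast markers (0 adjusted over the list alone; median 0.39, camera adjusted p 0.054). That list passed the test with quantile normalization (0.047), rescaled without the hormone genes (0.0085), with library weights (0.043), with voom (0.042) and over genes of at least 10 reads (0.046). It also passed without control library 1 (0.033) and without Bcas2 cKO libraries 3 (0.028) or 4 (0.0041). Among 7 Schwann cell and neuron markers Ngfr (0.77) rose and Th (-0.83) fell. The list's camera direction (up, adjusted p 0.98) and median (0.13) differed in sign from the mean (-0.004). The calls of C1qb, Irx1, Irx2, Col6a1, Th and Ngfr were lost in 4 to 6 of the 6 fits that left out a library, and that of Cd14 in 3.

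Immediate early and heat shock genes, many of which respond within minutes to depolarization or to tissue handling, were higher in Bcas2 cKO: 15 of 19 rose and none fell, also adjusted over the list alone. Their median log2 fold change was 1.77 (camera adjusted p 9.6e-10, adjusted p = 0.36 with an estimated correlation). They took 0.282 to 0.684% of the reads in control and 1.75 to 2.11% in Bcas2 cKO. Nr4a1, an orphan nuclear receptor, rose from 56.2 ± 33.8 to 310.0 ± 61.4 FPKM, Socs3, a feedback inhibitor of cytokine signalling, from 25.4 ± 10.96 to 137 ± 20.8 FPKM. The AP-1 gene Junb rose from 156 ± 70.3 to 738 ± 101 FPKM and Fosb from 156 ± 97.0 to 631 ± 124 FPKM. Between 8 and 15 members rose when a library was left out, with 8 without Bcas2 cKO library 4 and 9 without Bcas2 cKO library 5. Fosb lost its call in 4 of those 6 fits and with quantile normalization.

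Targets of p53 were higher as well, 6 of 19 having risen and none fallen (10 and 3 adjusted over the list alone), with a median of 0.43 (camera adjusted p 0.0024, adjusted p = 0.33 with an estimated correlation). Cdkn1a, the p21 inhibitor of the cell cycle, rose from 7.30 ± 1.52 to 30.5 ± 5.41 FPKM. Btg2, which is also an immediate early gene, rose by 1.69 on the log2 scale, Trp53inp1 by 1.35 and Phlda3 by 1.12. Of 27 interferon response genes 5 rose and none fell (13 and 0 adjusted over the list alone; median 0.40, camera adjusted p 9.8e-07, adjusted p = 0.36 with an estimated correlation), led by the transcription factor Irf1 (1.66), Ifit3 (1.20), Rtp4 (0.69) and Isg15 (0.56). Of 19 apoptosis regulators Birc3 (1.03) and Mcl1 (0.82) rose and Bcl2l1 (-0.27) fell (4 and 1 adjusted over the list alone; median 0.02, camera adjusted p 0.16). Of 30 genes of the unfolded protein response Ppp1r15a, which restores translation after stress, rose from 34.6 ± 11.4 to 123 ± 23.6 FPKM and none fell (1 and 0 adjusted over the list alone; median 0.04, camera adjusted p 0.55). Of 13 cell cycle genes Pcna (0.83) rose and none fell (1 and 0 adjusted over the list alone; median 0.08, camera adjusted p 0.16). Cdkn1a, Trp53inp1, Irf1, Birc3, Ppp1r15a and Pcna kept their calls without each library in turn. Btg2, Phlda3, Rtp4, Isg15, Mcl1 and Bcl2l1 lost theirs in 4 to 6 of the 6 fits and Ifit3 in 4 of the 5 in which it was tested.

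Genes that prolactin and related hormones raise in islets rose as a group. Of the 11 lactogen response genes 5 rose and none fell (8 and 0 adjusted over the list alone), with a median of 1.04 that does not depend on the fitted value of Tph1, the highest member (camera adjusted p 8.2e-05, adjusted p = 0.33 with an estimated correlation). Beside Tph1, the prolactin receptor gene Prlr rose from 19.3 ± 2.76 to 44.3 ± 3.36 FPKM. Tnfrsf11b, which encodes osteoprotegerin, rose from 2.58 ± 0.481 to 11.9 ± 4.39 FPKM and Tph2, the second tryptophan hydroxylase gene, from 0.440 ± 0.193 to 3.77 ± 1.004 FPKM. All 4 kept their calls without each library in turn. Of 11 measured genes on the list of progenitor and beta cell disallowed genes, Zfp36l1 (0.83) and Arhgdib (0.73) rose and none fell (2 and 0 adjusted over the list alone; median 0.28, camera adjusted p 0.0078, adjusted p = 0.33 with an estimated correlation). That list was not called over genes of at least 5 FPKM (adjusted p 0.27), Zfp36l1 lost its call without Bcas2 cKO library 3, and Arhgdib lost its call in 5 of the 6 fits.

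**Figure D3:**
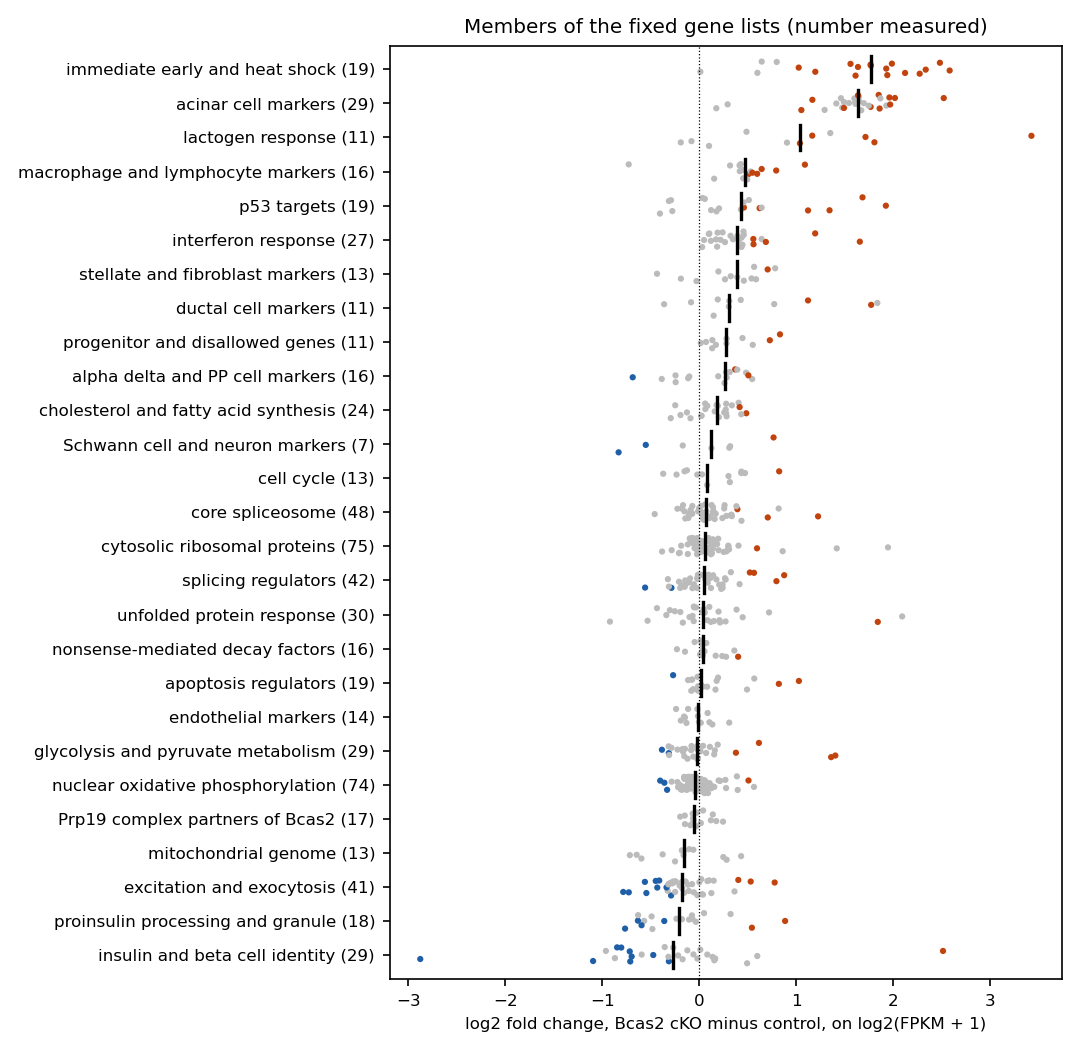
Log2 fold change of Bcas2 cKO minus control on log2(FPKM + 1) (horizontal axis) of each measured member of the 27 gene lists (rows, ordered by median, number measured in parentheses). Orange points rose, blue points fell and grey points were not called, and black bars are medians, from -0.27 for beta cell identity to 1.77 for immediate early genes. The medians of 8 lists, all between -0.02 and 0.07, changed sign under at least 1 other scaling.

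Lists of the splicing machinery were not called. None of the 17 measured Prp19 complex partners of BCAS2 passed the test (limma, 0 also adjusted over the list alone). The partners' median was -0.06 and mean -0.01 while camera placed them up (adjusted p 0.95). Cwc15 was 26.8 ± 3.75 and 25.5 ± 1.12 FPKM and Hspa8 231 ± 85.7 and 199 ± 23.1 FPKM. Of 48 core spliceosome genes 3 rose and none fell (2 and 0 adjusted over the list alone; median 0.07, camera adjusted p 0.062): Lsm5 (1.23), the U2 snRNP gene Sf3a2 (0.71) and the helicase gene Dhx38 (0.39). Of 42 splicing regulators 4 rose and 2 fell, also adjusted over the list alone (median 0.05, camera adjusted p 0.21). Srsf7 rose from 94.9 ± 21.1 to 174 ± 26.9 FPKM, Hnrnpa1 from 67.3 ± 8.65 to 117 ± 2.41 FPKM and Hnrnpl from 38.8 ± 2.44 to 57.9 ± 2.34 FPKM. Srrm4, a regulator of neural microexons, fell from 3.25 ± 0.654 to 1.87 ± 0.274 FPKM. The list of 16 nonsense-mediated decay factors was not called (median 0.04, camera adjusted p 0.19). Sf3a2, Hnrnpa1 and Hnrnpl kept their calls without each library in turn, and Lsm5, Dhx38, Srsf7 and Srrm4 lost theirs in 4 or 5 of the 6 fits. Dhx38 also lost its call after rescaling without the hormone genes. Gene totals hold no exon or junction values, so splicing itself was not analysed here. The core spliceosome list passed the test with median-of-ratios scaling (camera adjusted p 0.037), with quantile normalization (0.021), with voom (0.047), without control library 3 (0.019) and without Bcas2 cKO libraries 3 (0.034) or 5 (0.040). Its median turned negative after rescaling without the hormone genes.

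Metabolic lists were not called. Among 74 nuclear genes of oxidative phosphorylation Sdha (-0.40), Ndufb5 (-0.36) and Sdhc (-0.33) fell (0 adjusted over the list alone; median -0.04, camera adjusted p 0.75). None of the 13 genes of the mitochondrial genome passed the test (limma, 0 also adjusted over the list alone; median -0.16, camera adjusted p 0.36), mt-Co1 being 4102 ± 252 and 3933 ± 225 FPKM and mt-Cytb 2866 ± 340 and 2406 ± 210 FPKM. Of 29 genes of glycolysis and pyruvate metabolism 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p 0.98), with a camera direction and median (-0.02) below 0 and a mean (0.06) above 0. Gapdh rose from 3.87 ± 0.558 to 11.9 ± 1.48 FPKM, Fh1, the fumarase gene, from 17.6 ± 1.12 to 47.6 ± 11.1 FPKM and Pdhb from 24.2 ± 3.08 to 37.5 ± 0.925 FPKM. Gpd2 fell from 18.8 ± 1.99 to 14.1 ± 0.738 FPKM. Gapdh and the ribosomal gene Rps10 (0.60), the member that rose among 75 cytosolic ribosomal proteins, have many processed copies and stood at low FPKM, so their values are uncertain. No ribosomal gene fell (0 and 0 adjusted over the list alone; median 0.06, camera adjusted p 0.14). Of 24 genes of cholesterol and fatty acid synthesis Sqle (0.49) and Msmo1 (0.42) rose and none fell (0 and 0 adjusted over the list alone; median 0.19, camera adjusted p 0.062). The call of Gpd2 was lost under all 3 other scalings and in 5 of the 6 fits that left out a library. Those of Sdha, Sdhc, Ndufb5, Sqle, Msmo1 and Rps10 were lost in 4 to 6 of those fits. Ribosomal proteins passed the test as a list without control library 3 (camera adjusted p 1.9e-05) or Bcas2 cKO library 3 (0.011). Cholesterol and fatty acid synthesis did so without control library 1 (0.0019) or Bcas2 cKO library 3 (0.028), with library weights (0.035) and with voom (0.045). The mitochondrial genome did so without control library 1 (0.028) and with quantile normalization (0.039). Beside Gpd2 and Dhx38, the calls of C1qb, Irx1, Irx2, Rtp4, Isg15, Arhgdib, Sqle and Msmo1 were lost when rescaled without the hormone genes. Ptprn2 and Isg15 lost theirs with quantile normalization, as Fosb did, and Bcl2l1 with median-of-ratios scaling.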

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

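The block on shared numbers, voom and the minimum of 10 reads were chosen after the data were examined; all other alternatives were planned. The count of 1993 changed genes was 1964 to 2547 with a pseudocount of 0.1, median-of-ratios scaling, quantile normalization, library weights, robust estimation, voom or 10 reads, and 1579 to 1860 with 5 FPKM, no trend or rescaling without the hormone genes. It was 1144 with no filter, where 965 of the 1993 were called again and more low genes shared the adjustment, 407 with a minimum absolute log2 fold change of 1, and 878 to 1950 without single libraries. The log2 fold change of Bcas2 passed the threshold when rescaled without the hormone genes (-0.52) and with voom (-0.45). That rescaling also lowered the median of all genes, so its pass is not specific to Bcas2. Without single libraries the Bcas2 value ranged from -0.52 (past the threshold, without control 1) to -0.27, and in the other settings it did not pass. For voom and the fit without control 1 the cause was not tested. The 11 called lists became 9 to 14 in other settings, 11 to 15 without single libraries, and 0 with an estimated correlation in camera, which was as high as 0.793 for acinar markers. Fry called 10, without the acinar (adjusted p 0.078) and interferon (0.054) lists and with apoptosis regulators (0.012). No gene chosen by the rule and no list that passed the test did so in the opposite direction in any setting. Of the 89 called genes chosen by the rule, 13 lost the call without control 1, 27 without control 3, 41 without control 4, and 35, 36 and 39 without Bcas2 cKO 3, 4 and 5; smaller groups alone lower these counts. The correlation of deviations from the group means was -0.15 for number 3 and 0.05 for number 4. With so few libraries these values cannot tell whether equal numbers share a litter or batch. With the replicate block on the 4 libraries numbered 3 and 4, 646 genes changed, against 969 in the same libraries without it; a block on 1, 3 and 4 was not run because no Bcas2 cKO column is numbered 1. Count models were not run because the table holds FPKM. Of the calls, 52 had a mean under 10 reads. In simulated data most changes of 0.5 in log2 were missed.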

Other observations

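The tests of the patterns in this part were chosen after the results were seen, except the comparison of other splits of the libraries. Histone genes fell together. Among 109 gene families defined by the letters that begin their symbols, with at least 12 measured protein-coding members, the histone family alone was enriched in either direction at an adjusted p under 0.05 (Fisher's exact test, one-sided, adjusted p 3.4e-12 over 218 tests, which treats genes as independent). Of 26 measured histone genes 18 fell and none rose, with a median log2 fold change of -1.15, and between 18 and 20 fell under the 3 other scalings. Hist1h2bc, which was chosen after its values were seen, fell from 57.4 to 22.0 FPKM, whereas Hist1h1c, the most abundant member, was 121 and 97.1 FPKM (limma adjusted p 0.18). Genes outside the fixed lists that were chosen because they rose, and were not tested as a set, were Egr2 (2.18), Egr3 (2.25), Nr4a2 (2.29), Gem (2.65), Odc1 (2.53), Tnfaip3 (2.31), Cxcl1 (1.64) and Cxcl2 (1.67). Among falls chosen in the same way were Atp2a2, the calcium pump of the endoplasmic reticulum (-1.07, from 337 to 160 FPKM), Tmem215 (-1.50), Sez6l (-1.28), the free fatty acid receptor gene Ffar3 (-1.46) and Cox6a2, a cytochrome oxidase subunit (-1.53).

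The Y-linked gene Ddx3y was 18.7 ± 2.01 FPKM in control and 38.9 ± 2.07 FPKM in Bcas2 cKO, and Eif2s3y was 18.0 ± 0.918 and 13.1 ± 0.586 FPKM (SD, n = 3 each). The Y-linked genes Kdm5d and Uty were 2.73 to 3.55 and 4.19 to 4.66 FPKM over all 6 libraries. Xist, which female cells express, was at most 0.064 FPKM. All 6 libraries thus had the pattern of male mice, which argues against a difference in sex between the groups. Reads on noncoding genes that lie inside introns of protein-coding genes were 0.278 to 0.342% of the recovered reads in control and 0.343 to 0.394% in Bcas2 cKO, over 7171 such genes. At the depth of the shallowest library, 22894 to 24158 genes had at least 1 read in control and 25334 to 26681 in Bcas2 cKO. Reads on ribosomal RNA genes were 0.168 to 0.202% in control and 0.082 to 0.113% in Bcas2 cKO.

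Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 1993 changed genes, and the highest other gave 0. For the called lists 3 of the 10 gave as many as the 11 of the real split, and the highest other gave 12. With 10 splits no share can lie under 0.05.

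The tests of the beta cell identity falls replaced first versions built on the change of Ins2, under which acinar dilution and scaling had come out as able to account for the falls. They were replaced after that outcome was seen, because Ins2 did not pass the test in the main fit. Ins2 did pass without the trend in the variance and with voom, so this reason holds for the main fit only. The test of dilution then used the 9 falls alone, and was changed again to all members of the list because the falls had been chosen by their change. The test of mast and enterochromaffin markers had used their highest level, 2.42 FPKM for Slc18a1, and was undecided. It was changed to the highest rise because Slc18a1 was 3.02 FPKM in control.

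The 9 beta cell identity genes that fell did so beside a rise of acinar transcripts. A lower share of beta cells against every other cell type would raise the markers of those types alike, but the median log2 fold change was -0.0158 (SD 0.15 over 14 genes) for endothelial and 1.64 (SD 0.47 over 29 genes) for acinar markers. It was 0.27 for alpha, delta and PP cell, 0.31 for ductal, 0.39 for stellate and fibroblast and 0.48 for macrophage and lymphocyte markers. Over 12 genes taken as largely restricted to beta cells it was -0.53. Of these 12 genes 5 fell, all among the 9 falls above, and 0 rose, while Mafa was higher (0.60) but not called. A lower share of beta cells against some of the other types may therefore account for part of the falls, which ranged from -0.31 for Foxo1 to -2.88 for Trpm5. The share of reads on acinar marker genes would move every gene of the list by -0.04 in log2. Of the 95% intervals of all 29 members, 14 excluded that value, 11 below and 3 above it. By chance 1.45 were expected (binomial p 2.3e-11, which treats genes as independent). Among all 13723 genes tested, 4327 had an unadjusted limma p under 0.05. Intervals that exclude a value near 0 were thus common beyond this list, and the binomial p is not particular to beta cell genes. The dilution of -0.04 leaves out acinar RNA from other genes and the authors' scaling between libraries. The test therefore argues only against 1 shared shift of that size, and dilution as a part of the falls is not excluded. Under the 3 other scalings at least 8 of the 9 falls stayed called. These 9 genes had been chosen because they were called falls, and rescaling without the hormone genes lowered the median of all genes. Their kept calls therefore do not decide whether scaling contributed to the falls. Lower expression of these 9 genes within beta cells of the Bcas2 cKO group remains a hypothesis that these gene totals may reflect. A difference in handling was not tested. A difference in genetic background between wild-type controls and Cre carriers cannot be told apart from the loss of Bcas2, because no group carries the driver alone. That holds for every difference between the groups reported here.

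The rise of Tph1, Tph2, Prlr and Tnfrsf11b resembles a response to a lactogenic hormone. A hormone transcribed from a mouse gene in the preparation was not seen, since growth hormone, prolactin and placental lactogen genes had at most 2 reads in any library, and mast or enterochromaffin cells as the source of Tph1 were argued against by their other markers, which rose by at most 0.109 FPKM beside 10.2 FPKM for Tph1. A candidate explanation is a growth hormone sequence carried by some Cre transgenes. It cannot be told apart from the loss of Bcas2 here, because 0 rows of the table stand for Cre or human growth hormone, the labels do not name the Cre driver, and the controls are wild type. Controls that carry the driver alone would decide it.

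The fall of histone genes may come from fewer cells in S phase or from lower recovery of RNA without a poly(A) tail, which most histone transcripts lack. The 13 other measured S phase genes had a median of 0.28 (SD 0.30) against -1.15 for the histone genes, which argues against the first. Of these 13 only Pcna passed the test. The others had means under 5 FPKM in both groups, where the log2 scale used understates changes. For the second, the median of other RNAs without a tail was 0.18 over 2 genes with at least 10 reads, too few to tell, and -0.12 over all 5 measured, of which Scarna2 fell (-0.95, limma adjusted p 0.043). The share of ribosomal RNA reads was lower in Bcas2 cKO, and that of small nucleolar RNA genes was higher (0.0057 to 0.0075% in control and 0.0102 to 0.0119% in Bcas2 cKO). Reads on noncoding genes inside introns were also higher in Bcas2 cKO. The small nucleolar share therefore may not reflect the recovery of RNA without a tail and does not decide the question. A change in histone mRNA processing in Bcas2 cKO was not tested.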
